A study of Escherichia coli with 12 samples.

How the data were processed

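RNA-seq was performed on Escherichia coli MG1655, a K-12 laboratory strain, and on its isogenic relA mutant. The relA gene encodes a ribosome-associated synthetase of the alarmone ppGpp. Per the labels, cultures grew aerobically in LB at 37 °C, and trans-cinnamaldehyde (CNMA), the aldehyde of cinnamon oil, was added at an optical density of 0.1 from a 1 M stock in DMSO. The final concentration was 0.94 mM, or 0.25 of the minimal inhibitory concentration (MIC), for 30 or 60 min. The controls were untreated cultures labelled 0 min, so exposure, culture time and solvent change together in every comparison with a control. Exposure time and culture time also change together between 30 and 60 min. Total RNA was depleted of rRNA, made into stranded libraries and sequenced as 101 bp read pairs, per the labels. The 12 libraries formed 4 groups of 3 biological replicates: WT control, relA control, relA CNMA 30 min and relA CNMA 60 min.

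The deposited count table holds whole-number counts per gene, which the authors had not normalized, per the file headers. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.38.1, HISAT2, R 4.3.1 and DESeq 1.40.2. The genome build, the annotation, the counting program and its strand setting are not given in the sources used here, so rows of overlapping or antisense genes and of near-identical copies are uncertain. The table had 4534 rows, of which 4355 carried a gene symbol and 179 only an identifier. Of these rows, 4530 matched the reference gene table of the assembly ASM584v2, which was used only for names, gene lengths, RNA classes and gene order. No coordinates are given, because the build of the deposited table is not known. A further 6 count columns, headed as WT cells treated for 30 or 60 min, matched no sample label and were not used, so the difference in response between strains was not tested. A second table, the authors' deposited table of comparisons, holds log2 fold changes with standard errors, p-values and adjusted p-values, per the file headers. It covers CNMA against control at 30 and 60 min in WT and in the relA mutant, and its values are named as the authors' wherever they are printed.

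Library totals lay between 17209361 and 25487242 counts. A count of 0 in a library allows up to 3 counts, and this floor, taken per library, was used for rows at 0. It covers counting error only. No pair of replicates agreed within sampling noise, since the chi-square per degree of freedom over rows lay between 19.4 and 168.9.

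Rows were filtered with filterByExpr, which left 4437, and scaled by TMM. They were tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest, 2-sided) in R 4.3.3, in a single fit of the 4 groups with 8 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the rows tested within a comparison, with a threshold of 0.05, and a second count required a log2 fold change of at least 1 in size. Group levels are CPM, counts scaled to a common library size, on the TMM scale, as mean ± SD, unless library-size CPM is stated, and ± after a log2 fold change is its standard error. The 49 gene lists, fixed before the data were examined, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 49 lists. The same test with an estimated correlation was an alternative. Of 886 listed symbols, 882 had a row.

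Genes were named by a rule fixed before the data were examined. In each comparison these were relA, and the 5 highest and 5 lowest rows by log2 fold change with adjusted p under 0.05, a mean count of at least 50 and groups that did not overlap. They also included 3 members of each of the 6 lists with the smallest camera p, and the genes yqhD, nemA, frmA, soxS, marA, ibpA, spy, recA, rmf and fliC. A further rule, added after the data were seen, named the 5 highest and 5 lowest rows among the 245 that come before the row labelled crl. Other members named in the text were chosen after their values were seen.

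The alternatives were DESeq2 size factors, total counts only, leaving out rRNA, tRNA and tmRNA rows, no filter, a filter of 50 counts on average, DESeq2 1.42.0, a fit of only the groups compared, a replicate block, a test against a 1.5-fold change and leaving out each library in turn. Added after the data were seen were list tests with every label moved by 1, 2 or 3 rows or by part of the table, a run without the row labelled bamE, and comparisons of treated relA cells with WT control. The steps were tested on simulated counts for the real rows. For relA CNMA 30 min against relA control (4412 rows), the fit recovered 49.3% of rows changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold, and 1.88% of its calls were false. For 60 min against control (4408 rows) the shares were 61.2%, 89.6% and 100%, with 7.22% false. For 60 against 30 min (4309 rows) they were 53.7%, 92.5% and 97%, with 4.14% false. For relA control against WT control (4416 rows) they were 49.3%, 94% and 98.5%, with 5.29% false. Each simulation changed 67, 67 and 66 rows by these sizes, balanced between up and down and with a mean count of at least 50. In the data 82.2% of rows were called at 30 min against control. The simulations therefore do not give the share of false calls where most rows change. Python 3 with scipy and matplotlib was used for the remaining steps.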

Results

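The transcriptomes of 12 cultures were compared, 3 in each of 4 groups, to describe how the relA mutant responds to a sub-inhibitory dose of cinnamaldehyde. WT control libraries held 20186377 to 21014663 counts, relA control libraries 18879361 to 20083923, relA CNMA 30 min libraries 20137583 to 25487242 and relA CNMA 60 min libraries 17209361 to 23573442. The first principal component (64.4% of the variance) separated the untreated from the treated libraries and the second (19.7%) separated the control strains. The row labelled bamE took 16.4% ± 4.66 of the counts in relA control, against 4.31% ± 1.09 in WT control, 2.90% ± 1.26 at 30 min and 2.51% ± 0.58 at 60 min (SD, n = 3). Rows of rRNA genes took at most 0.35% of any library.

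The targeted gene was examined first. The row labelled relA (b2784) was not empty in the mutant: it held 73.9 ± 8.26 library-size CPM in relA control, 97.8 ± 8.35 at 30 min and 110 ± 6.41 at 60 min, against 119 ± 4.85 in WT control. The 3 rows just above it, mazG, mazF and mazE, which encode a nucleotide hydrolase and a toxin-antitoxin pair, held 0 counts in all 9 relA mutant libraries. In WT control they held 79.7 ± 4.40, 27.5 ± 5.44 and 14.7 ± 1.27 library-size CPM, at least 519.7-fold, 179-fold and 95.6-fold above the floor of 3 counts per library. The label relA therefore does not mark the row that was empty in the mutant, and the group labels are used as given. The row labelled ssrA, the abundant tmRNA, held 11 to 58 counts per library, and the last 2 rows of the table held 0 in all 12 libraries. In table order, the row bamE is followed by yfjF, ratA, smpB and ssrA, and which gene its reads come from was not tested. Leaving out tmRNA removed the row labelled ssrA and kept the row bamE.

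**Figure D1:**
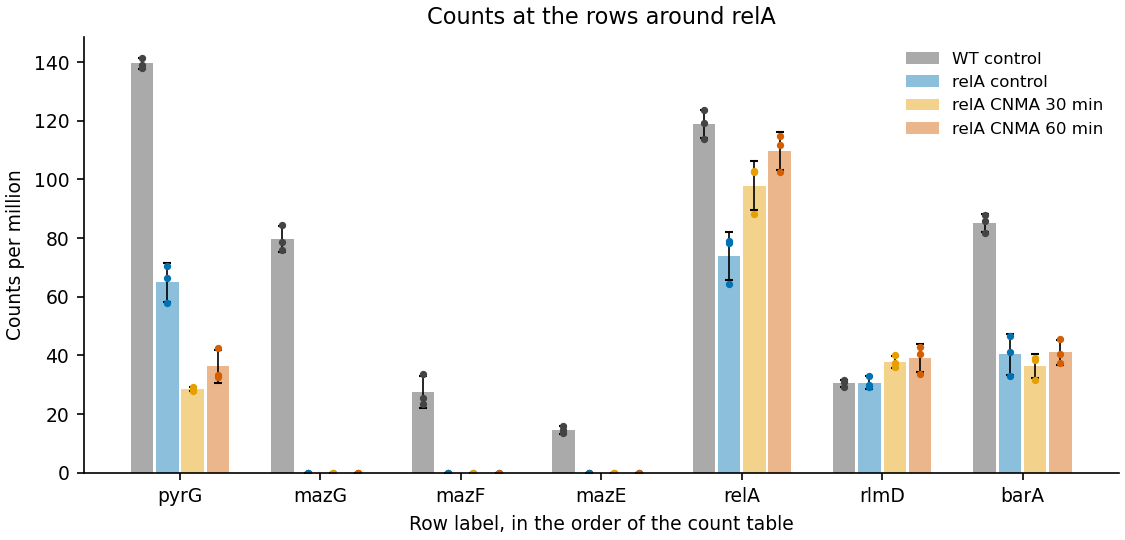
Library-size CPM (linear axis) at 7 neighbouring rows, in table order, for the 4 groups; bars are means, error bars SD and points the 3 libraries of each group. Rows mazG, mazF and mazE are at 0 in all 9 relA mutant libraries, whereas the row relA is not.

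How members of the fixed lists varied together was measured along the table, after the data had been seen. Among the 245 rows before crl, members correlated best at their own label (mean r across libraries 0.784, against 0.65 with reads taken 1 row above). From crl to insH21 the values were 0.499 at the label and 0.444 1 row above. After insH21 they were 0.263 at the label and 0.439 2 rows above. Names after insH21 are therefore row labels only. Names from crl to insH21 are treated alike as a caution, although members there correlated best at their own label, and the move by part shifts them by 1 row. Rows before crl are described separately. A list is described where its call also held with labels moved by 1 or 2 rows and by part, unless stated otherwise. Where members stand side by side in the table, as ATP synthase rows do, a move keeps many of the same rows. For such lists, holding under a move is a weak check on the labels. With labels 3 rows above, calls were lost for iron-sulfur assembly (adjusted p = 0.564 at 30 min and 0.314 at 60 min), the OxyR regulon (0.16, 0.247 and, between control strains, 0.0663), ppGpp (0.388 and 0.39), cell division from 30 to 60 min (0.434), and TCA cycle (0.133) and sulfur assimilation (0.102) between control strains.

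The 2 rows that follow each row named below, in table order, are given in brackets here: prpB (prpC, prpD), prpC (prpD, prpE), prpD (prpE, codB), frmB (frmA, frmR), frmA (frmR, yaiO), entD (fepA, fes), fepA (fes, ybdZ), entC (entE, entB), entE (entB, entA), ahpC (ahpF, uspG), ahpF (uspG, ybdR), ybfL (ybfD, ybgA), rmf (fabA, ycbZ), flgA (flgB, flgC), fabD (fabG, acpP), comR (bhsA, ldtC), yddW (gadC, gadB), gadC (gadB, pqqL), marA (marB, eamA), ydhF (ydhL, nemR) and ydhL (nemR, nemA). Further down the table they are nemA (gloA, rnt), sufD (sufC, sufB), sufC (sufB, sufA), spy (astE, astB), astB (astD, astA), fliC (fliD, fliS), gatB (gatA, gatZ), gatA (gatZ, gatY), mglC (mglA, mglB), mglA (mglB, galS), psuK (fruA, fruK), fruA (fruK, fruB), yfaH (glpQ, glpT), glpQ (glpT, glpA), zipA (cysZ, cysK), recA (pncC, mltB), ftsB (ygbE, cysC), cysC (cysN, cysD), cysH (cysI, cysJ), yghB (yqhC, yqhD) and yqhC (yqhD, dkgA). The last are yqhD (dkgA, yqhG), rpsO (truB, rbfA), mdh (argR, yhcN), rpsH (rpsN, rplE), rpsN (rplE, rplX), rplX (rplN, rpsQ), yiaW (aldB, yiaY), yibH (yibI, mtlA), yidE (ibpB, ibpA), ibpA (yidQ, yidR), tnaC (tnaA, tnaB), atpC (atpD, atpG), atpD (atpG, atpA), soxS (soxR, ryjA), lysU (dtpC, cadA), dtpC (cadA, cadB), cadA (cadB, cadC), treC (treB, treR) and mgtL (mgtA, ridA).

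The response of the relA mutant after 30 min was broad. Ribosomal protein rows rose together: 43 of 54 were higher and 7 lower (the same counts when adjusted over the list alone), with a median log2 fold change of 2.66 (camera adjusted p = 9.13e-21, and adjusted p = 0.0699 with an estimated correlation). The size of this rise depends on the control: the list lay at -1.90 in relA control against WT control, and the same treated libraries had a median of 0.58 at 30 min and 0.48 at 60 min against WT control, a comparison added after the data were seen. Row rplX went from 223 ± 42.2 to 5307 ± 275 CPM, a log2 fold change of 4.57 ± 0.13, and row rpsN by 4.31 ± 0.10. All 9 ATP synthase rows rose (median 2.57, adjusted p = 3.37e-06, and adjusted p = 0.0699 with an estimated correlation), among them atpC by 3.08 ± 0.09 and atpD by 3.04 ± 0.11. Of 13 fatty acid biosynthesis rows 11 rose (median 1.94, adjusted p = 7.12e-05, and adjusted p = 0.0699 with an estimated correlation), with fabD at 3.33 ± 0.17. Of 29 rows for cell division and the cell wall 25 rose and 4 fell (median 1.26, adjusted p = 6.68e-05, and adjusted p = 0.182 with an estimated correlation), led by the peptidoglycan precursor enzymes murF (2.84 ± 0.12) and murE (2.57 ± 0.10). Against WT control the medians at 30 min were smaller: 1.19 for ATP synthase, 0.63 for fatty acid biosynthesis and 0.48 for cell division, which was not called there (adjusted p = 0.0814).

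Aminoacyl-tRNA synthetases were called higher, with 18 of 23 rows higher (median 1.04, adjusted p = 0.000655, and adjusted p = 0.0915 with an estimated correlation). The aerobic respiratory chain had 18 of 22 higher (1.82, 0.00672, and adjusted p = 0.426 with an estimated correlation). Lipopolysaccharide synthesis had 20 of 23 higher (1.02, 0.00672, and adjusted p = 0.234 with an estimated correlation). With total counts as the only scaling, the medians of the synthetases and of lipopolysaccharide synthesis turned to -0.08 and -0.11. Against WT control their medians were 0.69 and 0.69, and lipopolysaccharide synthesis was not called (adjusted p = 0.0863). SoxRS rows were split, 6 higher and 5 lower of 13 (median 0.27, or -0.85 with total counts only, adjusted p = 0.0291, and adjusted p = 0.182 with an estimated correlation). Against WT control 9 of them were higher and 2 lower (median 0.86, camera adjusted p = 0.000175, and adjusted p = 0.0703 with an estimated correlation).

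Other groups fell at 30 min. Of 36 iron acquisition rows 24 fell and 6 rose (median -2.19, camera adjusted p = 5.16e-07, and adjusted p = 0.234 with an estimated correlation). Among them row fepA went from 530 ± 32.3 to 9.27 ± 0.82 CPM and row entD fell (-5.78 ± 0.13 on the log2 scale). Of 15 acid resistance rows 10 fell (median -1.58, adjusted p = 0.00949, and adjusted p = 0.188 with an estimated correlation), and row gadC fell (-7.94 ± 0.19). OxyR regulon rows fell in 8 of 11 cases (median -1.94, adjusted p = 0.00546, and adjusted p = 0.216 with an estimated correlation). Rows for phenylpropionate and cinnamate degradation fell in 24 of 29 cases (median -1.15, adjusted p = 0.0434, and adjusted p = 0.349 with an estimated correlation), a call lost without relA control replicate 2 or 30 min replicate 2 or 3 (adjusted p = 0.0539, 0.0571 and 0.0503). Of 13 iron-sulfur assembly rows 7 fell and 4 rose (median -0.32, adjusted p = 0.0434, and adjusted p = 0.352 with an estimated correlation), a call lost without 30 min replicate 2 or 3 (adjusted p = 0.0942 and 0.0539). Of these lists, acid resistance and OxyR were higher in relA control than in WT control, and acid resistance (-0.97, adjusted p = 0.426), OxyR (-0.47, 0.481) and cinnamate degradation (-0.50, 0.388) were not called at 30 min against WT control.

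Row yghB rose by 10.43 ± 0.15, from 11.5 ± 0.37 to 15861 ± 537 CPM (adjusted p = 1.87e-15), and the row after it, yqhC, by 7.22 ± 0.23. The next row, yqhD, rose by 3.92 ± 0.18. Rows ydhF (7.20 ± 0.16) and ydhL (7.20 ± 0.24) stand just above nemR and nemA, and row nemA itself rose by 1.94 ± 0.16. Row frmA rose by 6.42 ± 0.17. As a whole the aldehyde and electrophile list, with 15 of 30 rows higher and 10 lower, was not called under the deposited labels (camera adjusted p = 0.149). Against WT control this list was called higher at 30 min (camera adjusted p = 0.045, and adjusted p = 0.437 with an estimated correlation). There 13 rows were higher and 10 lower, with a median of 0.03. Rows yghB, ydhF and ydhL, which stand just above members of this list, are outside it under those labels. Row mdh also rose, by 6.60 ± 0.35. The deepest falls, beside gadC, were at yiaW (-8.72 ± 0.31) and at rows prpD (-7.89 ± 0.13) and prpC (-7.82 ± 0.31), and row tnaC went from 24.8 ± 8.95 to 0.042 ± 0.038 CPM. That level of tnaC rests on 0 or 1 counts per library, and its fitted change moved from -9.10 to -8.49 without 30 min replicate 1. Without 30 min replicate 3 the change of yiaW was -9.52.

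**Figure D2:**
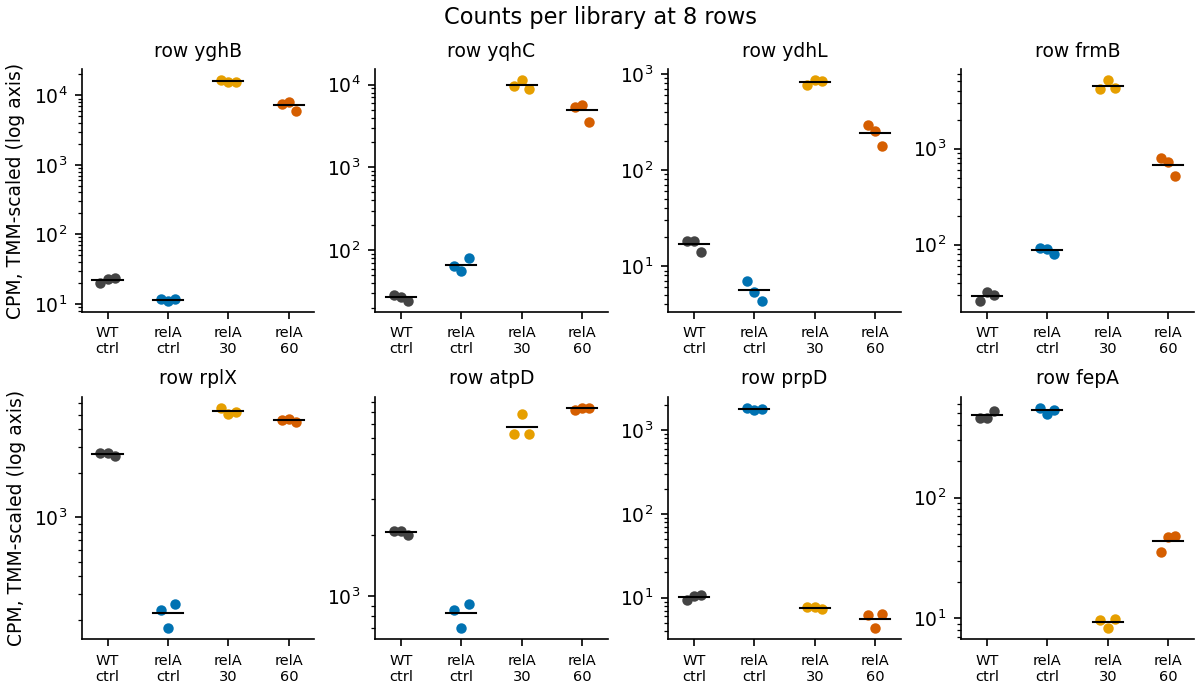
TMM-scaled CPM (log axes) per library at 8 rows in the 4 groups (n = 3 each; lines are means). Row yghB lies near 11.5 in relA control and near 15861 at 30 min, and row prpD is high in relA control alone, at 1791.

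Among the rows before crl, 125 of 238 changed at least 2-fold at 30 min, 79 up and 46 down. The pyruvate dehydrogenase complex rose, with aceF at 4.68 ± 0.10, aceE at 3.22 ± 0.07 and lpd at 3.14 ± 0.08. The elongation factor gene tsf rose by 3.82 ± 0.13 and the glucose dehydrogenase gene gcd by 4.08 ± 0.17. The acyl-CoA dehydrogenase gene fadE (-5.01 ± 0.22) and the peroxide response gene yaaA (-3.52 ± 0.10) fell.

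Of the remaining genes fixed in advance, rmf rose by 1.29 ± 0.15 and marA (-1.39 ± 0.17), spy (-5.36 ± 0.20) and fliC (-1.73 ± 0.18) fell. Rows soxS (0.33 ± 0.13, adjusted p = 0.0273) and recA (0.29 ± 0.09, adjusted p = 0.00742) rose slightly, and ibpA did not pass (0.19 ± 0.15, adjusted p = 0.252). The call of soxS was lost without relA control replicate 1 or 3 or 30 min replicate 2 (adjusted p = 0.0514, 0.0768 and 0.0815). With total counts only, soxS, recA and ibpA turned negative. In all, 3647 of 4437 rows changed, 1542 up and 2105 down, and 2449 by at least 2-fold. Groups did not overlap at 83.4% of rows, where chance gives 10%. The median over all rows was -0.33 with TMM and -1.46 with total counts only, and changes are relative to these. With total counts only, 645 rows were higher and 3261 lower, and with DESeq2 1757 were higher and 1827 lower.

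After 60 min 12 of the lists called at 30 min were again called with labels moved. Ribosomal protein rows were higher in 43 of 54 cases and lower in 5 (median 2.48, camera adjusted p = 1.2e-20, and adjusted p = 0.0632 with an estimated correlation). All 9 ATP synthase rows rose (median 2.54, adjusted p = 8.13e-07), a call that held with adjusted p = 0.0481 with an estimated correlation. Rows for cell division and the cell wall rose in 27 of 29 cases (median 1.67, adjusted p = 1.45e-07, and adjusted p = 0.0632 with an estimated correlation). Fatty acid biosynthesis rose in 12 of 13 (1.68, adjusted p = 0.000117) and aminoacyl-tRNA synthetases in 17 of 23 (1.14, adjusted p = 0.000187), each with adjusted p = 0.0632 with an estimated correlation. The aerobic respiratory chain rose in 19 of 22 (1.54, adjusted p = 0.0101, and adjusted p = 0.437 with an estimated correlation). Lipopolysaccharide synthesis rose in 21 of 23 (0.93, or -0.10 with total counts only, adjusted p = 0.0101, and adjusted p = 0.255 with an estimated correlation). The SoxRS list, called at 30 min, missed the threshold at 60 min, with 9 of 13 higher and 2 lower (median 1.02, adjusted p = 0.0509, and adjusted p = 0.198 with an estimated correlation). Against WT control it was called at 60 min, with 11 higher and 2 lower (median 1.42, camera adjusted p = 0.000958, and adjusted p = 0.111 with an estimated correlation). Against WT control the medians at 60 min were 1.17 for ATP synthase, 0.85 for cell division and 0.54 for fatty acid biosynthesis, the last not called (adjusted p = 0.0744), nor was lipopolysaccharide synthesis (0.56, adjusted p = 0.114). The counts of these lists were unchanged when adjusted over the list alone.

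Lists lower at 60 min included iron-sulfur assembly, with 9 of 13 rows lower (median -1.29, camera adjusted p = 0.00483), where the suf row sufC (-5.15 ± 0.12) and row sufD (-3.91 ± 0.12) fell. OxyR rows were lower in 9 of 11 cases (-2.11, adjusted p = 0.0102) and cinnamate degradation rows in 26 of 29 (-1.55, adjusted p = 0.0107). Each of these 3 lists had adjusted p = 0.255 with an estimated correlation. Acid resistance rows were lower in 9 of 15 (-2.61, adjusted p = 0.0144, and adjusted p = 0.17 with an estimated correlation). Iron acquisition rows were lower in 20 of 36 and higher in 12 (-0.84, adjusted p = 0.0153, and adjusted p = 0.502 with an estimated correlation). Against WT control, OxyR (-0.49, adjusted p = 0.705), cinnamate degradation (-0.91, 0.143) and acid resistance (-0.83, 0.516) were not called at 60 min. The small ppGpp list, with relA and 2 other rows higher, was called at both times but not with labels moved (adjusted p = 0.256 and 0.233 by part), and at 30 and 60 min had adjusted p = 0.21 and 0.177 with an estimated correlation.

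Row yghB was again highest (9.30 ± 0.14, from 11.5 ± 0.37 to 7236 ± 1089 CPM), followed by dtpC (7.12 ± 0.25), cadA (6.70 ± 0.29), yqhC (6.19 ± 0.22) and yibH (5.79 ± 0.23). Row lysU, just above dtpC, rose by 4.80 ± 0.24. The deepest falls were at prpC (-8.36 ± 0.32), prpD (-8.30 ± 0.14), gadC (-8.10 ± 0.20), yddW (-7.75 ± 0.22) and astB (-7.20 ± 0.32). Before crl, 129 of 238 rows changed at least 2-fold. Of these aceF (4.81 ± 0.10) and aceE (3.52 ± 0.07) rose, while fadE (-4.47 ± 0.21), the copper oxidase gene cueO (-3.50 ± 0.13) and the periplasmic protease gene degP (-3.40 ± 0.11) fell. The authors' deposited WT values at 60 min were 1.10 for aceF and 1.29 for aceE. For fadE, cueO and degP they were -3.49, -1.69 and -2.57. Among the genes fixed in advance, yqhD (2.75 ± 0.17), nemA (0.59 ± 0.15), frmA (3.59 ± 0.15), soxS (0.70 ± 0.13), recA (0.34 ± 0.09) and rmf (1.16 ± 0.15) rose. Rows marA (adjusted p = 1.67e-06), spy (-6.40 ± 0.21) and fliC (-1.10 ± 0.17) fell, and ibpA did not pass (0.06 ± 0.15, adjusted p = 0.705). With total counts only, nemA, soxS, recA and ibpA turned negative. In all, 3626 rows changed, 1618 up and 2008 down (746 and 3105 with total counts only, 1819 and 1806 with DESeq2), and 2449 at least 2-fold. Groups did not overlap at 81.6% of rows, where chance gives 10%. The median over all rows was -0.24, or -1.26 with total counts only.

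The comparison of 60 with 30 min asked which rows and lists moved with time in treated relA cells. Without untreated cultures at 30 and 60 min, effects of longer exposure and of longer culture cannot be told apart here. Iron acquisition rows rose in 28 of 36 cases (median 1.45, camera adjusted p = 2.4e-18, and adjusted p = 0.374 with an estimated correlation), with entC at 2.57 ± 0.12 and entE at 2.39 ± 0.13. Rows for secondary carbon sources rose in 35 of 47 (median 1.37, adjusted p = 2.32e-13, and adjusted p = 0.449 with an estimated correlation). The highest of these, glpQ (6.28 ± 0.75) and mglC (5.77 ± 0.96), were spread widely at 60 min, at 62.8 ± 51.3 and 99.8 ± 90.3 CPM, and fell to 5.46 and 4.89 without 60 min replicate 3. Flagellar and chemotaxis rows rose in 27 of 52 cases, or 28 when adjusted over the list alone (median 0.64, adjusted p = 1.24e-05, and adjusted p = 0.449 with an estimated correlation). Among these flgA rose by 4.86 ± 0.42, and fliC by 0.63 ± 0.19, a call lost without 60 min replicate 3 (adjusted p = 0.109). Sulfur assimilation rows were split, 11 higher and 6 lower of 27, or 13 and 7 adjusted over the list alone (median 0.24, adjusted p = 0.000169, and adjusted p = 0.39 with an estimated correlation). Rows cysC (5.20 ± 0.30) and cysH (4.58 ± 0.30) were the furthest up.

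Aldehyde and electrophile rows fell back from 30 to 60 min in 15 of 30 cases (16 adjusted over the list alone), with 1 higher (median -0.38, camera adjusted p = 0.000776, and adjusted p = 0.39 with an estimated correlation). Rows frmA (-2.83 ± 0.14), frmB (-2.73 ± 0.15), nemA (-1.35 ± 0.15) and yqhD (-1.17 ± 0.16) fell. The chaperone genes dnaK (-1.91 ± 0.11) and dnaJ (-1.63 ± 0.12), before crl, also fell, as did gcd (-3.01 ± 0.16), while the ferrichrome receptor gene fhuA rose by 2.28 ± 0.08. Other extreme rows were yfaH (5.97 ± 0.65), mglA (5.76 ± 0.89) and treC (5.46 ± 0.55), and comR (-4.27 ± 0.39), fruA (-3.62 ± 0.15), yidE (-3.32 ± 0.17) and psuK (-3.09 ± 0.17). Without 60 min replicate 3, yfaH, mglA and treC were at 5.08, 4.90 and 4.83. Cell division rows were called higher (17 of 29, or 18 adjusted over the list alone, adjusted p = 0.00507, and adjusted p = 0.449 with an estimated correlation), led by ftsB and zipA, rows that stand 1 or 2 above ygbE, cysC, cysZ and cysK. That call was lost with labels 2 rows above (adjusted p = 0.101) and without 60 min replicate 1 (adjusted p = 0.0707). Row spy fell (-1.04 ± 0.23), while marA, ibpA, recA and rmf did not pass (adjusted p = 0.673, 0.572, 0.72 and 0.555), and soxS (0.37 ± 0.13) passed with all libraries (adjusted p = 0.0336) but not without 30 min replicate 1 or 3 or 60 min replicate 1 or 3 (adjusted p = 0.101, 0.104, 0.0943 and 0.0959). In all, 1657 rows changed, 807 up and 850 down (971 and 600 with total counts only, 801 and 970 with DESeq2), and 589 at least 2-fold. Tested against 1.5-fold, 583 passed. Groups did not overlap at 45.4% of rows, where chance gives 10%.

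The untreated strains were compared to describe how relA control cultures differed from WT control cultures without cinnamaldehyde. Ribosomal protein rows were lower in relA control than in WT control in 41 of 54 cases and higher in 5 (6 adjusted over the list alone), with a median of -1.90 (camera adjusted p = 1.26e-26). This call held with adjusted p = 0.0461 with an estimated correlation. Rows rpsO (-3.85 ± 0.13) and rpsH (-3.71 ± 0.13) were lower. ATP synthase rows were lower in 8 of 9 cases (-1.28, adjusted p = 0.000888, and adjusted p = 0.0757 with an estimated correlation). Fatty acid biosynthesis rows were lower in 11 of 13 (-1.09, adjusted p = 0.000712, and adjusted p = 0.0895 with an estimated correlation). Cell division rows were lower in 24 of 29 (-0.82, adjusted p = 0.000314, and adjusted p = 0.192 with an estimated correlation). All 6 rows of the neighbours of relA were lower (adjusted p = 1.81e-06, and adjusted p = 0.0461 with an estimated correlation), including the 3 at 0. Those 3 weigh heavily in this call, which therefore does not show a wider effect on the neighbours. On library-size CPM row rlmD was alike in both, at 30.6 ± 1.18 in WT control and 30.8 ± 2.09 in relA control.

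Higher in relA control were TCA cycle rows, in 14 of 16 cases (median 2.31, camera adjusted p = 0.00178, and adjusted p = 0.416 with an estimated correlation). OxyR rows were higher in 7 of 11 (0.79, adjusted p = 0.000239, and adjusted p = 0.0906 with an estimated correlation), with rows ahpC at 3.72 ± 0.14 and ahpF at 2.54 ± 0.09. Acid resistance rows were higher in 9 of 15 (0.78, adjusted p = 0.000712, and adjusted p = 0.0547 with an estimated correlation), with gadC at 4.75 ± 0.16. Sulfur assimilation rose in 17 of 27 (0.83, adjusted p = 0.00245, and adjusted p = 0.211 with an estimated correlation). Glyoxylate and acetate metabolism rose in 5 of 7 (0.74, adjusted p = 0.0123, and adjusted p = 0.101 with an estimated correlation). Secondary carbon sources rose in 27 of 47 (0.73, adjusted p = 0.0148, and adjusted p = 0.667 with an estimated correlation). The furthest up were prpC (7.77 ± 0.30), prpD (7.44 ± 0.13), gatB (6.88 ± 0.39) and gatA (6.43 ± 0.42), and prpB (6.36 ± 0.20). Below the 3 empty rows, the furthest down were mgtL (-4.18 ± 0.16) and ybfL (-4.14 ± 0.26).

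Before crl, 66 of 238 rows differed at least 2-fold between the control strains, 16 up and 50 down. The genes aceF (-3.48 ± 0.09) and lpd (-1.82 ± 0.08) were lower in relA control, and yaaA (3.28 ± 0.10), thrA (1.57 ± 0.13) and fadE (1.47 ± 0.18) were higher. Rows spy (3.36 ± 0.17) and frmA (1.49 ± 0.14) were higher, rmf (-0.81 ± 0.15) was lower, and yqhD (0.32 ± 0.16, adjusted p = 0.0948) and nemA (-0.10 ± 0.15, adjusted p = 0.567; positive with total counts only) did not pass. Row soxS was higher (0.53 ± 0.13) and ibpA did not pass (adjusted p = 0.0966; positive with total counts only). Rows marA, recA and fliC passed with all libraries (adjusted p = 0.0212, 0.045 and 0.0237) and lost their calls without WT control replicate 1 (0.106, 0.126 and 0.0636), among others. Row relA was lower (-1.11 ± 0.09). In all, 2879 rows changed, 1452 up and 1427 down (2312 and 861 with total counts only, 1329 and 1586 with DESeq2), and 1332 at least 2-fold. Tested against 1.5-fold, 1561 passed. Groups did not overlap at 71.9% of rows, where chance gives 10%. The share of counts at the row bamE, given above, was also higher in relA control than in WT control.

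**Figure D3:**
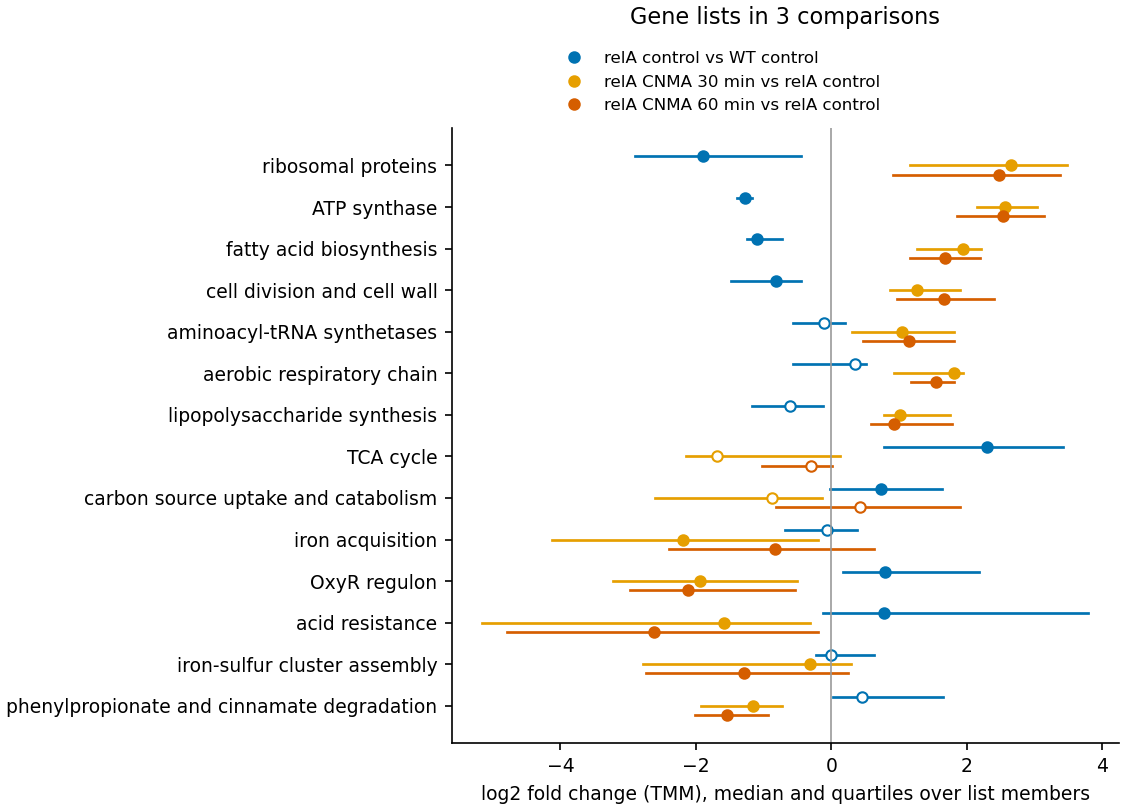
Median log2 fold change (points) and quartiles (lines) over the members of 14 gene lists in 3 comparisons; filled points had a camera adjusted p under 0.05 at the preset correlation, open points did not. Ribosomal protein rows lie at -1.90 in relA control against WT control and at 2.66 and 2.48 in treated against untreated relA cells; with total counts only, medians of the synthetases at 30 min and of lipopolysaccharide synthesis at both times turn negative.

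The 30 and 60 min responses share their control libraries. Across 4437 rows their log2 fold changes had r = 0.87 (covariance 2.85), where 20 simulations of unchanged groups against those controls gave r = 0.46 (covariance 0.026). Rows higher in both numbered 1362 and rows lower in both 1771. The simulations gave 0 for each, but no row was changed in them, so that 0 sets no reference for shared calls. Independent lists of those sizes would share 562 and 953. The relA controls also enter the 30 min response and the strain comparison with opposite signs. There r was -0.54 (covariance -1.22), against -0.48 (covariance -0.027) in the simulations. In opposite directions 1890 rows were called, against 1185 for independent lists. The simulations gave 0, which for the same reason sets no reference. The simulations cover the spread between libraries of a group, and that spread gave little of the covariance. They do not cover a state common to all 3 control libraries. With 3 control libraries the responses could not be set against separate control sets of 2, so part of the excess may come from such a state.

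The difference between strains in the response was not tested here, because treated WT libraries were not analysed here: the 6 count columns headed as treated WT cells match no sample label. In the authors' deposited table, 1685 rows at 30 min and 1868 at 60 min changed at least 2-fold in WT, and 2407 and 2426 in the relA mutant. The median log2 fold change of ribosomal protein rows in the authors' deposited table was 0.17 at 30 min and 0.49 at 60 min in WT, and 2.94 and 2.67 in the mutant.

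**Figure D4:**
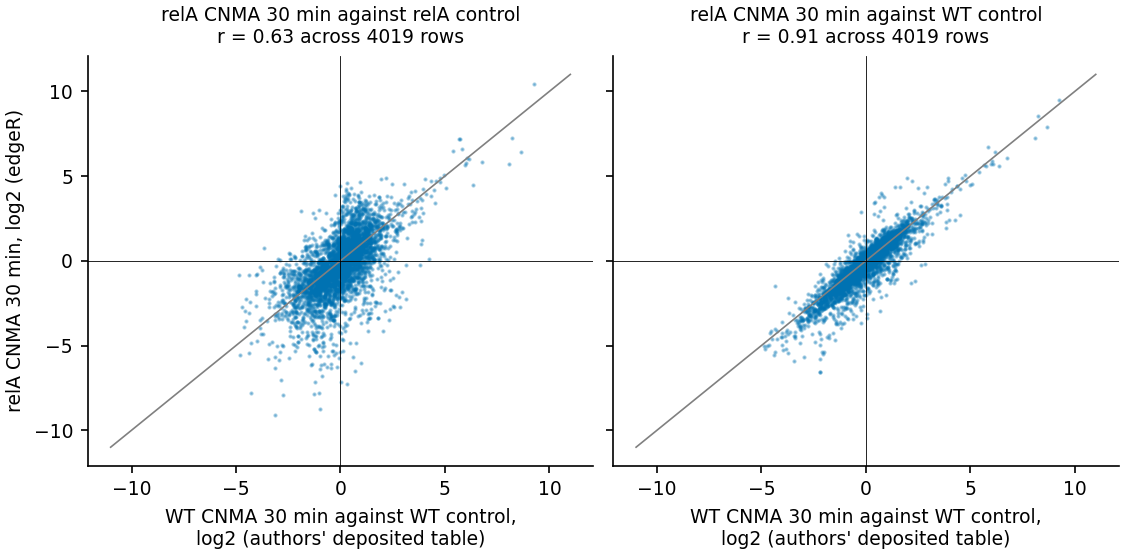
Log2 fold change at 30 min in WT from the authors' deposited table (horizontal) against that of treated relA cells computed here (vertical), relative to relA control (r = 0.63) and to WT control (r = 0.91, raised by WT control libraries that both axes share, to an extent not computed here); each point is 1 of 4019 rows with a mean count of at least 50, without mazE, mazF and mazG.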

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

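The tests of label placement and of the control strains below were chosen only after the result was seen, as were the tests on other splits. Treated relA cells differed between 60 and 30 min in 5 gene lists by the test of the difference itself, at the preset correlation and with labels moved. Exposure time and culture time cannot be told apart in these differences. The median log2 differences, under the deposited labels only, were 0.64 for flagella and chemotaxis, 0.24 for sulfur assimilation and -0.38 for aldehyde and electrophile detoxification. They were 1.45 for iron acquisition and 1.37 for secondary carbon sources. None of these 5 calls held with an estimated correlation (adjusted p = 0.449, 0.39, 0.39, 0.374 and 0.449 in that order). The same test also called cell division and the cell wall (adjusted p = 0.00507), a call lost with labels 2 rows above (adjusted p = 0.101), without 60 min replicate 1 (adjusted p = 0.0707) and with an estimated correlation (adjusted p = 0.449). Groups of 3 were not tested for libraries far from the others.

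Splits of 6 libraries into 3 and 3 number 10 per comparison, the real one included, too few for a share under 0.05. With edgeR on the 6 libraries alone, 1 of 10 splits, the real one, gave the highest count in each comparison. It called 3620 rows for 30 min against control, 3511 for 60 min against control, 1380 for 60 against 30 min and 3012 for the control strains. The highest of the other splits called 0 in each, with at most 17, 24, 202 and 70 rows at an unadjusted p under 0.05.

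The first pattern weighed is that rows mazG, mazF and mazE, and not row relA, were empty in the mutant. A slip of names against counts in the table is argued against, since in 31 of 31 windows of 150 rows counts followed the length of the labelled gene better than that of its 8 neighbours (median r 0.41, against 0.11). Correct labels with a loss of these 3 genes would leave 73.9, 97.8 and 110 library-size CPM at row relA in the 3 mutant groups. The count columns of these groups are headed ∆relA. That argues against correct labels at this locus, unless part of relA was left in place, which was not tested. Intervals displaced against the sequence the reads were aligned to, as when 2 versions of a genome sequence are mixed, remain open. After insH21, 36 of 48 lists varied together better with reads taken 2 rows above their labels (exact sign test, p = 0.000717). That offset was chosen on the same lists and libraries, so this p-value cannot decide whether the labels there are correct. The list of neighbours of relA went the other way (0.483 at the label, 0.211 2 rows above), and it holds the 3 empty rows. The displacement is offered as a hypothesis only: it was read from the mean correlation after insH21 (0.439 at 2 rows above, 0.263 at the label), with the offset taken at its highest value, so those values do not test it. The versions used are not given in the sources used here.

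The second pattern is the large difference between the untreated strains. A strain difference of the same size in every condition is argued against. The difference between treated relA cells and the authors' treated WT values, both relative to WT control, was regressed on the difference between the controls. Its slope was -0.0481 (95% interval -0.0719 to -0.0248) at 30 min and 0.0894 (0.0611 to 0.117) at 60 min. These intervals resample rows, not cultures, so they do not measure the spread between cultures. Counts taken by the row bamE are argued against as the whole cause: with total counts only they would lower all other rows of relA control, where 2312 rows were higher and 861 lower. Another growth state of the relA control cultures and a loss of relA that acts in untreated cultures only cannot be told apart. The fall of ribosomal protein rows (median -1.90) and the slope of -0.0481 at 30 min could arise under either. Each strain has 1 set of untreated cultures at 0 min, which keeps both open. Either may enlarge the response of the relA mutant measured against its own control.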

How the results depend on the processing

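Tests with moved labels, without the row bamE and against WT control were chosen after the data were seen, the others before. Of the counts of changed genes under the alternatives, 62 stayed within 1.5 times the reported count and 2 did not: tested against 1.5-fold, 583 genes differed between 60 and 30 min and 1561 between the control strains, by construction of a stricter test. Leaving out 1 library gave 3483 to 3551 genes for 30 min against control, 3516 to 3582 for 60 min, 1325 to 1657 for 60 against 30 min and 2628 to 2730 for the control strains, against 2754 to 3906, 2760 to 3851, 583 to 1771 and 1561 to 3173 over the other alternatives. The share of higher rows among changed rows stayed within counting error of the reported share in 48 cases and moved in 16. Each list call and each named gene was counted once per alternative. Of list calls 802 kept their side of the threshold, 78 lost it and 0 changed direction. With an estimated correlation alone, 41 list calls were lost and 3 were kept. Of named genes 2907 kept their side of the threshold, 46 lost it, 8 gained it and 13 reversed. Reversed with total counts only were, at 30 min, soxS (-0.80), ibpA (-0.92) and recA (-0.84), at 60 min, nemA (-0.43), soxS (-0.32), ibpA (-0.96) and recA (-0.69), and between control strains nemA (0.32) and ibpA (0.12). At 60 min ibpA also reversed with a filter of 50 counts (-0.0098) and without relA control replicate 3 (-0.0093, to 0.17 without replicate 2), and nemA between control strains without WT control replicate 3 (0.0174) or relA control replicate 3 (0.033, to -0.24 without WT control replicate 1). For these the cause was not tested.

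Replicate numbers share only a number. With the replicate block, 3613, 3583, 1518 and 2816 genes changed in the 4 comparisons, in the order above. The lowest correlations of same-numbered pairs were -0.06, -0.16, -0.11 and -0.31, and for 2, 1, 0 and 1 of 3 libraries the same-numbered partner was the best correlated.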

Other observations

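The comparisons and label moves in this part were chosen after the data were seen. Treated relA cells set against WT control rather than their own control gave 3388 changed rows at 30 min (1941 at least 2-fold) and 3517 at 60 min (2115 at least 2-fold). Ribosomal protein rows then had medians of 0.58 (camera adjusted p = 0.00565, and adjusted p = 0.474 with an estimated correlation) and 0.48 (adjusted p = 0.0121, and adjusted p = 0.431 with an estimated correlation). TCA cycle rows had medians of 1.16 (13 of 16 higher, adjusted p = 0.0179, and adjusted p = 0.513 with an estimated correlation) and 1.58 (16 of 16 higher, adjusted p = 0.00288, and adjusted p = 0.413 with an estimated correlation). Of the lists called against relA control, those of acid resistance (adjusted p = 0.426 and 0.516), OxyR (0.481 and 0.705), cinnamate degradation (0.388 and 0.143), lipopolysaccharide synthesis (0.0863 and 0.114) and ppGpp (0.238 and 0.163) were not called against WT control at 30 and 60 min. Neither were cell division at 30 min (0.0814) and fatty acid biosynthesis at 60 min (0.0744). In the authors' deposited table the median of TCA cycle rows was 2.11 and 1.32 in treated WT and -1.40 and -0.11 in the treated mutant, each against its own control.

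With labels moved by 0, 1 or 2 rows by part of the table, ribosomal protein rows were higher at 30 min in 52 of 54 cases and aminoacyl-tRNA synthetase rows in 23 of 23. Heat shock rows fell from 30 to 60 min in 16 of 21 cases under these labels (adjusted p = 2.18e-12), where the deposited labels gave adjusted p = 0.117, and labels 3 rows above gave adjusted p = 0.0568. With an estimated correlation, run with the deposited labels only, the adjusted p was 0.477. The move by part was drawn up from how members of these same lists varied together in these same libraries. Counts and p-values under the moved labels therefore depend on that choice and do not test it.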
